A study of Caenorhabditis elegans with 6 samples.

How the data were processed

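H3K9me3, a histone mark of silent chromatin, was profiled by CUT&Tag in round spermatids sorted from male C. elegans 8 to 10 h after heat stress. CUT&Tag uses an antibody to bring a transposase to the mark, and the DNA cut there is sequenced. Per the labels' protocols, each library was made from 300000 spermatids, to which 30 human 293-F cells were added as a spike-in. The 6 libraries fall into 2 groups of 3 by the strain given in the labels. The group called WT carries tagged csr-1a in a him-8 background, and the other group carries a csr-1a deletion in the same background. The titles number the libraries of each group as biological replicates 1 to 3, without saying what a number shares.

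The deposited table holds 1 signal value per gene and library for 19999 genes, scaled by the authors to the human spike-in (named RRPM in the deposited table). The formula behind the scaling and the human read counts are not given in the sources used here, so the error of a library's factor could not be computed. Per the submitters' processing notes, fastp 0.20.1, Bowtie2 2.3.5.1, bedtools and the human build GRCh38 were used. The worm build, the gene annotation, the handling of duplicate reads and the assignment of reads to genes are not given in the sources used here. Because all genes of a library share one factor, an error in that factor moves every gene of the library alike. No unstressed, input or control-antibody library was analysed here, so neither the effect of heat stress nor the background level was measured.

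Within each library the values were whole multiples of one step, within 0.001 reads, for 100% of values. Dividing by this step gave 5564907 to 11739878 reads per library and a median of 141 to 368 reads per gene. These reads were used to describe depth only. In WT replicates 1 and 3 only 70 and 71 values lay at or below 20 steps, under the 100 set for testing the step, so no count test was run. The tests planned for a signal scale were used instead.

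Genes above 0 in at least 3 of the 6 libraries were tested, which kept 19993 genes and left out 6. Values were taken as log2(value + 11.66), where the pseudocount is the 10th percentile of all non-zero values. Fold changes on this scale understate the change of low genes. Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The main fit kept the spike-in scale. A separate fit first subtracted each library's median log2 value, which removes one factor per library. Differences per library (the genome-wide median, the X chromosome minus autosomes, autosomal arms minus centres) were tested with exact two-sided permutation tests, whose smallest p for 3 against 3 is 0.1. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.

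Chromosome, order and length of genes came from the RefSeq table of assembly WBcel235, used for these properties only since the build of the deposited values is not known. By symbol 18965 genes matched and by sequence name 928 more, and 106 did not match. Of the latter, 12 were assigned to the mitochondrial genome by name. Arms were the outer 30% of genes' span on each side of an autosome, and centres the middle 40%.

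Before the data were examined, 18 gene lists were fixed: major sperm protein, spermatogenesis, oogenesis and maternal, neuronal, muscle, cuticle collagen, intestinal, developmental transcription factor, heat shock, Argonaute and small RNA pathway, histone methylation factor, histone, F-box and MATH/BTB, chemoreceptor, C-type lectin, nuclear hormone receptor, ribosomal protein and piRNA genes. The piRNA list had 0 members in the table, which left 17. Of 401 members listed by name, 389 were found. Lists were tested with camera in limma, which asks whether a list moved differently from other genes, with an inter-gene correlation preset at 0.01. They were tested again with an estimated correlation and with fry, which asks whether a list moved at all on balance.

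Named genes followed a rule also fixed before the data were examined. It takes csr-1 first. It then takes genes past the threshold with all 3 mutant libraries beyond all 3 WT libraries and a mean above the median of tested genes, namely the 10 largest falls and rises on the spike-in scale and the 5 largest of each relative to the library median. Where fewer pass, the list is filled by the smallest unadjusted p among such genes. Last come the 3 members of each list with the highest mean log2 value. Only 1 rise on the spike-in scale qualified, and no further gene had all mutant libraries above all WT libraries, so that list could not be filled. Among all genes, 40 share all 6 values with another one, among them fbxa-151 and fbxa-78, so their reads cannot be told apart. Families of near-identical genes may share reads in the same way.

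The tests were checked on simulated data for csr-1a mutant against WT, with 19993 genes of which 100 were raised and 100 lowered. All changed genes were drawn from those with a mean above the median, so recovery at lower genes was not measured. Each simulated change had the same size in every mutant library. In the data mutant replicate 2 lay closer to WT than the other mutant libraries did. Recovery of changes that differ between mutant libraries was not measured, so the shares below may overstate it for the real data. With each library scaled to the same total, 90% of raised and 92% of lowered genes were recovered at 2-fold, and 100% of both at 4-fold, with 0 other calls. Relative to the library median, 94% and 99% were recovered at 2-fold, with 7 other rises. On the spike-in scale the simulated libraries kept their real totals, so raised genes were set against the shared fall. There 0% of raised and 100% of lowered genes were recovered at 2-fold and 41% and 100% at 4-fold, and 19600 other genes were called lower at 2-fold.

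Alternatives covered the pseudocount, the filter, the trend and robust options of limma, a replicate block, leaving out each library, equal library totals, quantile normalization, mean in place of median levels, and arms as the outer 20%. The edgeR test on recovered reads, planned for the case that reads could be recovered by the set rule, was not run.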

Results

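The series addressed how loss of CSR-1A, an isoform of the Argonaute protein CSR-1, changes H3K9me3 across the genome of spermatids after heat stress. H3K9me3 CUT&Tag signal over 19999 genes was compared between 3 WT and 3 csr-1a mutant libraries of sorted round spermatids. Recovered reads per library were 11739878, 8950134 and 11219344 in WT replicates 1 to 3 and 7660878, 9218929 and 5564907 in mutant replicates 1 to 3. The titles call the libraries biological replicates. Whether they came from separate cultures is not stated, so p-values measure the spread between these samples. All levels are spike-in scaled reads per gene (RRPM).

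Over csr-1 itself, on chromosome IV, the signal was 283, 480 and 229 RRPM in WT replicates 1 to 3 and 85.1, 224 and 53.3 in mutant replicates 1 to 3. It fell in the mutant by 1.52 on the log2 scale (SE 0.38, limma adjusted p = 6.3e-04, lower in 3 of 3 mutant libraries). Limma pools the spread over genes, which share each library's factor on this scale, so this p overstates the evidence. The exact permutation p for the level of csr-1 was 0.1 (n = 3 each). Without mutant replicate 3 the change was -1.11 and did not pass (limma adjusted p = 0.070; range over all alternatives 3.56e-08 to 0.070). Relative to the library median csr-1 stood at 4.12 ± 0.30 in WT and 3.61 ± 1.35 in the mutant (SD, n = 3 each, exact permutation p = 0.6). By library it was 3.9, 4.46 and 4.01 in WT replicates 1 to 3 and 3.31, 5.09 and 2.44 in mutant replicates 1 to 3. Chromatin signal over the gene does not show whether CSR-1A was lost, so it checks neither group label.

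H3K9me3 signal was lower in the csr-1a mutant over nearly the whole genome. The median gene had 30.5 ± 11.8 RRPM in the mutant and 79.0 ± 25.9 in WT (SD, n = 3 each), so WT was 2.59-fold higher, and each mutant library lay below each WT library (exact permutation p = 0.1, the smallest that 3 against 3 allows). Of 19993 genes tested, 17398 (87.02%) fell, 1 rose and 2594 did not pass the test (limma, adjusted p under 0.05). The median log2 change was -1.01, with an interquartile range from -1.21 to -0.83. In 18203 genes (91.0%) all mutant libraries were below all WT libraries, where chance gives 5% for this direction and 10% for either. These genes are not independent, because every gene of a library carries that library's spike-in factor. Limma pools the spread over all genes, so its small p-values on this scale repeat the same difference between libraries. They are not separate evidence for each gene. The fall in total signal, to 43.5% of WT, combined fewer recovered reads (70.3% of WT, exact permutation p = 0.2, n = 3 each) with a lower signal per read (0.146 ± 0.019 against 0.247 ± 0.120, exact permutation p = 0.1, n = 3 each). The count of fallen genes was 2228 without mutant replicate 1, 2520 without mutant replicate 3 and 6936 without WT replicate 1. The median log2 level was 6.395, 6.898 and 6.1 in WT replicates 1 to 3 and 5.222, 5.799 and 5.067 in mutant replicates 1 to 3. Same-numbered libraries of the 2 groups thus ranked alike in level. With 3 libraries per group, whether the numbers pair them stays open. The main fits did not pair them.

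**Figure D1:**
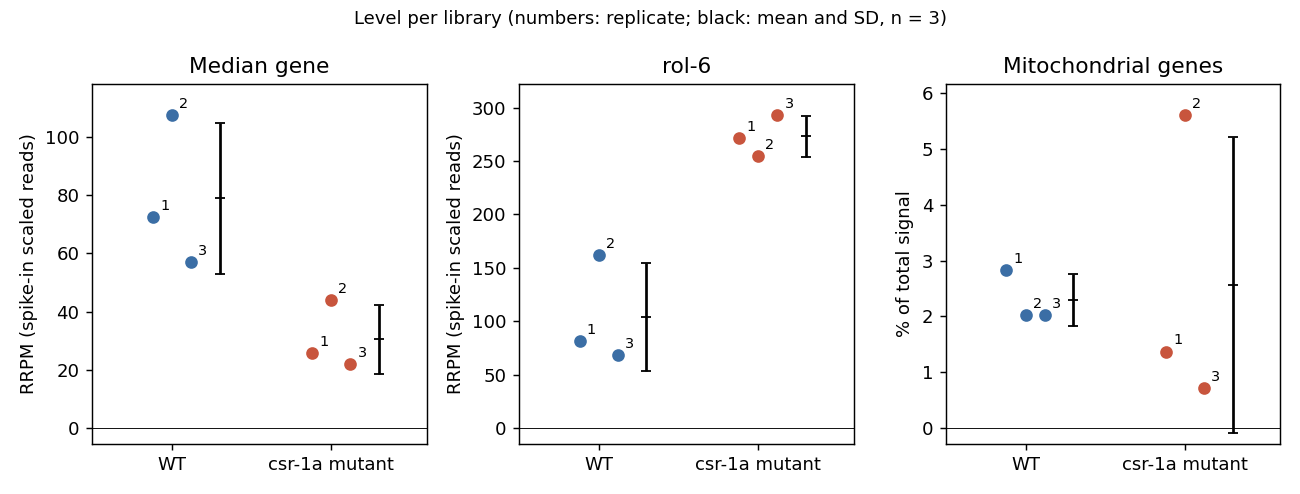
Level of each library (points, numbered by replicate) with the group mean and SD (black, n = 3). Left, RRPM of the median gene, 21.9 to 44.01 in the mutant and 56.9 to 107.6 in WT. Middle, RRPM of rol-6, 254.8 to 293.1 in the mutant and 68.5 to 161.8 in WT. Right, mitochondrial genes as a percent of total signal, 5.61% in mutant replicate 2 and 0.72% to 2.83% in the others.

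The largest fall among genes named by the rule was at rga-1, with 32.2 ± 28.7 RRPM in the mutant and 150 ± 35.5 in WT (SD, n = 3 each, log2 change -2.05, SE 0.39). Next came ubr-5, a ubiquitin ligase gene (-2.04), T04A8.7 (-2.03) and chc-1, the clathrin heavy chain gene, with 87.1 ± 54.5 RRPM against 364 ± 105 (-2.03). They were followed by pfd-1, a prefoldin subunit gene (-2.02), ogt-1, which encodes O-GlcNAc transferase (-2.02), and larp-1, a La-related RNA-binding protein gene (-2.01). The last of the 10 were ifg-1, the translation factor eIF4G gene (-2.005), rib-2, needed for heparan sulfate synthesis (-2.004), and ari-1.1 (-2.003). All 10 had a limma adjusted p of 1.69e-04. With library totals made equal, which removes the shared fall, their log2 changes were -0.91 to -1.16 with limma adjusted p values of 0.079 to 0.080, so none passed.

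One gene, rol-6, rose on the spike-in scale. It encodes a cuticle collagen on chromosome II and had 273 ± 19.2 RRPM in the mutant against 103.8 ± 50.6 in WT, a 2.63-fold difference (SD, n = 3 each, log2 change 1.39, SE 0.38, limma adjusted p = 0.0015, higher in 3 of 3 mutant libraries). With equal library totals the rise was 2.51 (SE 0.21, limma adjusted p = 0.0070). The closest tested genes on either side, T01B7.9 and T01B7.8, changed by -0.17 and -0.05 on that scale and did not pass. The highest of the 10 nearest tested genes, mak-1, was at 0.02. In simulated libraries with the same shared fall, limma on the spike-in scale called 0% of genes raised 2-fold and 41% of those raised 4-fold. The raised genes there were all above the median level.

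**Figure D2:**
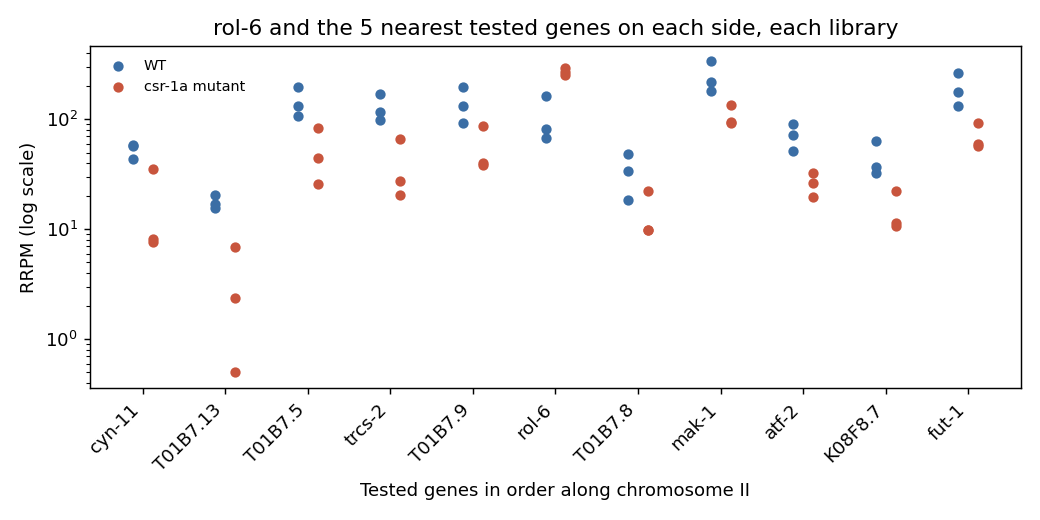
RRPM (log axis) of rol-6 and the 5 nearest tested genes on each side along chromosome II, one point per library, WT in blue and csr-1a mutant in red. At rol-6 the 3 mutant points lie above the 3 WT points, while the log2 change on the spike-in scale is below 0 at each of the 10 neighbours.

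The number of genes called relative to the rest of the genome depended on how libraries were scaled. Relative to the library median, 1010 genes fell and 901 rose (limma). With each library scaled to the same total before the pseudocount was added, 0 genes fell and 1 rose, rol-6 (limma; at an unadjusted p under 0.05, 4470 were lower and 1296 higher). Quantile normalization also gave 0 and 1. All 1010 falls kept their direction with equal totals, with a median log2 change of -0.751 (median SE 0.189) against -0.594 (0.148), while the median of the 901 rises went from 0.634 (0.166) to 0.323 (0.150) and 808 kept their direction. Over all tested genes the median change was 0.089 relative to the library median and -0.099 with equal totals. Part of both shifts is therefore a moved zero point. With quantile normalization the medians of the falls and rises were -0.602 (0.153) and 0.468 (0.141). The 5 largest relative falls were rga-1 (-0.95), ubr-5 (-0.93), T04A8.7 (-0.93), chc-1 (-0.93) and pfd-1 (-0.92), all with a limma adjusted p of 0.037. The 5 largest relative rises were rol-6 (2.49), the uncharacterised C03A7.2 (1.03), bli-1, a cuticle collagen gene (0.92), F07B7.7 (0.91) and grl-27, a ground-like protein gene (0.90), the last 4 with a limma adjusted p of 0.037. For these 9 genes other than rol-6 the changes with equal totals were about as large, from -1.149 to -0.908 for the falls and from 0.858 to 1.053 for the rises. Their SE was 0.177 to 0.286 in place of 0.159 to 0.25 and their limma adjusted p 0.079. On the spike-in scale these 4 were slightly lower in the mutant, from -0.07 for C03A7.2 to -0.20 for grl-27, and did not pass. Leaving out any library except mutant replicate 2 ended all relative calls but rol-6, whereas without mutant replicate 2 there were 3239 falls and 5528 rises. With equal totals and without that library, an alternative chosen after seeing the data, 5992 genes fell and 2619 rose.

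**Figure D3:**
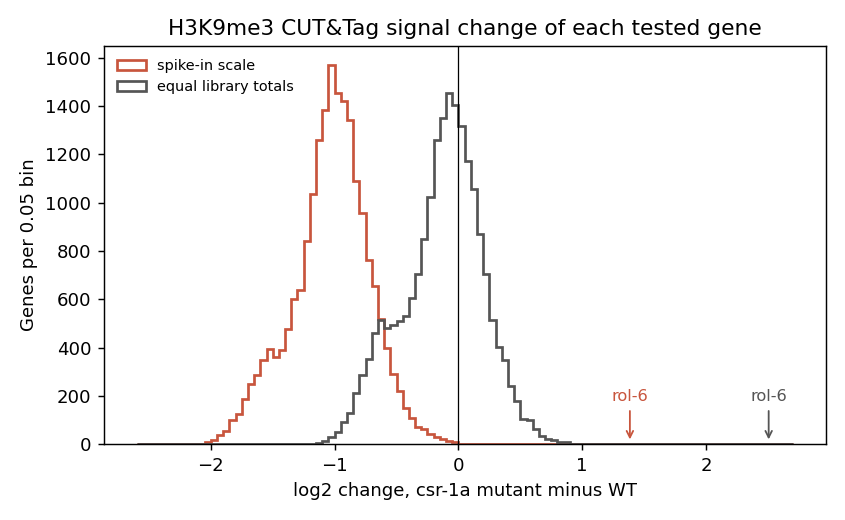
Histogram of the log2 change (csr-1a mutant minus WT) of 19993 tested genes, in bins of 0.05, on the spike-in scale (red) and with equal library totals (grey). The medians are -1.01 and -0.10, and rol-6 is marked at 1.39 and 2.51.

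The fall reached all 6 chromosomes. The share of tested genes that fell was 88.2% on I, 87.9% on II, 90.8% on III, 88.7% on IV, 84.4% on V and 83.7% on X. The X chromosome carried less signal than the autosomes in both groups, 19.7 RRPM per kb in WT against 41.7 to 46.2. Males carry fewer copies of X than of each autosome, and no input library was analysed. A lower DNA dose and a lower mark on X therefore cannot be told apart. In log2 units X lay -0.65 ± 0.08 from the autosomes in WT and -0.45 ± 0.04 in the mutant, a difference of 0.20 (SD, n = 3 each, exact permutation p = 0.1). With means in place of medians this difference was -0.016 (exact permutation p = 0.7), and with genes above the median level 0.045 (exact permutation p = 0.4), so its direction was not settled. Its size depended on the pseudocount, at 0.099 with the smallest and 0.207 with the median one (exact permutation p = 0.1 for each). Autosomal arms, where H3K9 methylation is known to be richer in worms, held 43.7 ± 14.5 RRPM per kb in WT and centres 41.8 ± 13.3 (SD, n = 3). In the mutant they held 18.3 ± 5.83 and 15.4 ± 6.37. Of 9391 arm genes 82.3% fell, and of 7775 centre genes 93.9%. Arms minus centres was 0.06 ± 0.04 in WT and 0.21 ± 0.09 in the mutant, a difference of 0.15 on the log2 scale (SD, n = 3 each, exact permutation p = 0.1), or 0.062 with the median pseudocount (exact permutation p = 0.2).

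Signal fell further than at other genes on 4 of the 17 gene lists by camera with a preset correlation. All 4 calls were lost with an estimated correlation (adjusted p = 0.878 for each). The estimate was 0.73 to 0.93 over the lists, and it includes the spike-in factor that all genes of a library share. With such values no list was called, so the loss does not tell the lists apart. With equal totals, which removes that factor, none of the 4 was called with an estimated correlation either (camera adjusted p = 0.39 to 0.42). The members named for each list are among those with the highest mean log2 levels, not the largest changes. All 42 histone methylation factor genes fell, also adjusted over the list alone, with a median of -1.50 (camera adjusted p = 1.5e-11; adjusted p = 0.878 with an estimated correlation). Examples are lin-13, a zinc-finger gene of the synMuv group, with 114 ± 61.4 RRPM in the mutant and 394 ± 136 in WT, the chromatin remodeller let-418 with 88.3 ± 46.6 against 277 ± 106, and set-9 with 111 ± 41.03 against 321 ± 148 (SD, n = 3 each). All 79 ribosomal protein genes fell (79 adjusted over the list alone), with a median of -1.37 (camera adjusted p = 2.9e-13; 0.878 likewise), such as rps-15 with 403 ± 222 against 1258 ± 438 RRPM (-1.69) and rpl-39 with 249 ± 65.1 against 548 ± 158 (-1.09, close to the median gene). Of 57 Argonaute and small RNA pathway genes 51 fell (51 adjusted over the list alone), with a median of -1.39 (camera adjusted p = 3.4e-07; 0.878 likewise). The Argonaute genes alg-4 (211 ± 38.04 against 487 ± 180, -1.12) and alg-2 (288 ± 47.5 against 581 ± 235, -0.92, less than the median gene) were among them, and wago-10 (248 ± 5.14 against 395 ± 147, -0.58, limma adjusted p = 0.13) was not. All 33 oogenesis and maternal genes fell (33 adjusted over the list alone), with a median of -1.37 (camera adjusted p = 1.2e-05; 0.878 likewise). Of its 3 members highest by mean log2 level, fbf-2, an RNA-binding protein gene (264 ± 85.4 against 637 ± 193, -1.23), fell more than the median gene, and the kinase gene mbk-2 (537 ± 72.7 against 1104 ± 397, -0.97) and mex-3 (121 ± 30.9 against 260 ± 93.6, -1.004) fell less. With equal totals only lin-13, let-418, set-9 and rps-15 of the members named lay below the median of all genes, and the others were at -0.078 (fbf-2) to 0.568 (wago-10), among them rpl-39 at 0.06, mex-3 at 0.11 and mbk-2 at 0.20. No named member passed on that scale. The 4 list medians there were -0.62, -0.61, -0.46 and -0.39, below the median of all genes at -0.10. Adjusted over the list alone on that scale, 28, 1, 30 and 13 of their members were lower and 0, 0, 4 and 0 higher, so the Argonaute list held members of both directions.

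Signal fell less than at other genes on 6 lists by camera with a preset correlation. All 6 calls were lost with an estimated correlation (adjusted p = 0.878 for each), which includes the factor that all genes of a library share. With equal totals, which removes that factor, none of the 6 was called with an estimated correlation either (camera adjusted p = 0.22 to 0.39). Among 177 cuticle collagen genes 63 fell (14 adjusted over the list alone), 1 rose, rol-6, and 113 did not pass, with a median of -0.71 (camera adjusted p = 9.8e-23; adjusted p = 0.878 with an estimated correlation). The fallen col-147 had 726 ± 109 RRPM in the mutant against 1363 ± 535 in WT, while col-99 (401 ± 9.15 against 612 ± 234) and col-94 (273 ± 15.6 against 433 ± 163) did not pass (SD, n = 3 each). Of 239 C-type lectin genes 153 fell (125 adjusted over the list alone; median -0.86, camera adjusted p = 1.3e-09, 0.878 likewise). The lectin gene clec-197 fell (387 ± 82.2 against 821 ± 270, -1.03, close to the median gene) and clec-78 did not pass (1111 ± 89.5 against 1958 ± 697). Of 414 F-box and MATH/BTB genes 299 fell (259 adjusted over the list alone; median -0.88, camera adjusted p = 4.7e-08, 0.878 likewise), and bath-21 did not pass (379 ± 30.5 against 599 ± 180). Of 82 histone genes, whose copies are nearly identical, 36 fell (28 adjusted over the list alone; median -0.74, camera adjusted p = 6.4e-08, 0.878 likewise). Of 1322 chemoreceptor genes 1145 fell (1144 adjusted over the list alone, median -0.94, camera adjusted p = 2.5e-05, 0.878 likewise), such as str-81 (763 ± 84.0 against 1395 ± 457). Their fallen share, 86.61%, was close to the 87.02% of all tested genes, so the count does not set this family apart. With a replicate block the chemoreceptor call was lost (camera adjusted p = 0.21). Of 35 intestinal genes 25 fell (24 adjusted over the list alone; median -0.91, camera adjusted p = 0.0037, 0.878 likewise), among them the yolk protein genes vit-6 (289 ± 24.4 against 535 ± 202) and vit-3 (207 ± 46.2 against 418 ± 130). With equal totals the medians turned positive for collagens (0.29), lectins (0.17), histones (0.16), F-box genes (0.06) and intestinal genes (0.04), and stayed negative for chemoreceptors (-0.05).

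**Figure D4:**
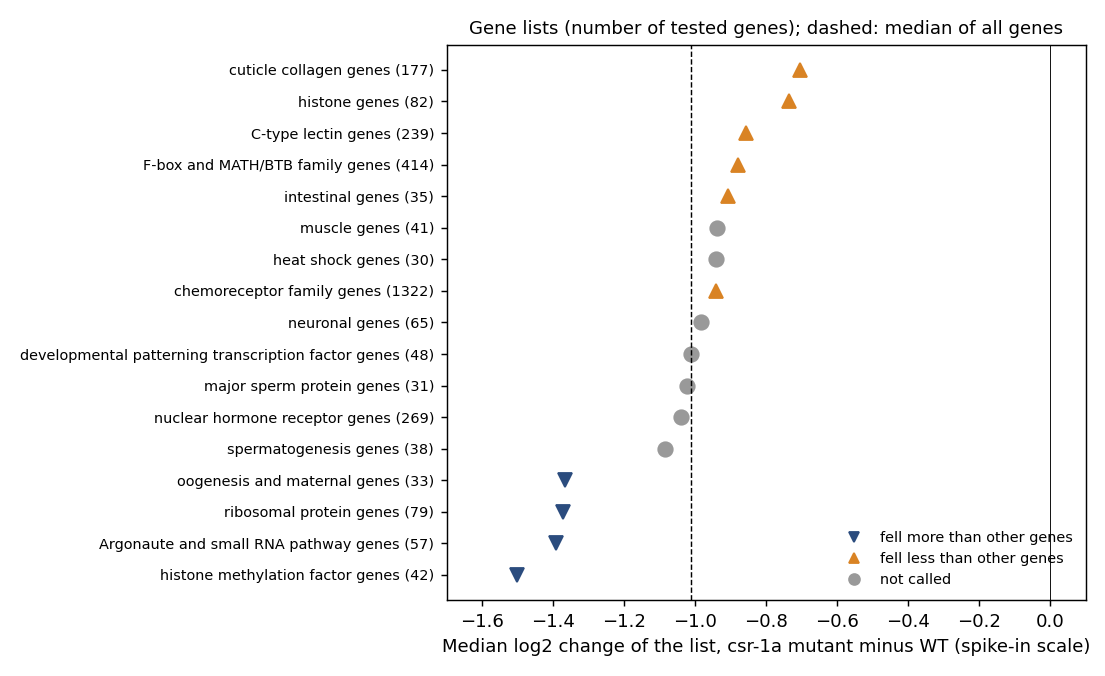
Median log2 change (csr-1a mutant minus WT, spike-in scale) of each of 17 gene lists, with the number of tested genes in brackets. Triangles mark lists that fell more (4, pointing down) or less (6, pointing up) than other genes by camera with a preset correlation, circles lists not called, and the dashed line the median of all genes (-1.01). No list was called with an estimated correlation, which on this scale includes each library's shared factor. With equal totals none was called with an estimated correlation either (lowest camera adjusted p = 0.22). With equal totals 8 of the 17 medians lie above 0.

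The other 7 lists were not called by camera on the spike-in scale with all 6 libraries and no replicate block, although most of their members fell. With a replicate block the muscle list was called as falling less than other genes (camera adjusted p = 0.0089). Spermatid genes were among them. Of 31 major sperm protein genes, a family of near-identical copies, 28 fell (29 adjusted over the list alone), with a median of -1.02 (camera adjusted p = 0.11), such as msp-77 (43.3 ± 8.81 against 103.7 ± 28.1 RRPM). Of 38 spermatogenesis genes 37 fell (38 adjusted over the list alone), with a median of -1.08 (camera adjusted p = 0.30), such as fer-1, needed for sperm membrane fusion (296 ± 56.8 against 650 ± 227), and spe-15, a myosin gene (595 ± 128 against 1278 ± 564). Of 30 heat shock genes 27 fell (28 adjusted over the list alone), with a median of -0.94 (camera adjusted p = 0.19). The mitochondrial chaperone gene hsp-6 fell (660 ± 191 against 1518 ± 532), and the co-chaperone gene sti-1 did not pass (1158 ± 44.5 against 1832 ± 638). The genes of somatic tissues that fell were 60 of 65 neuronal genes (60 adjusted over the list alone; median -0.98, camera adjusted p = 0.19), 36 of 41 muscle genes (36; median -0.94, camera adjusted p = 0.13) and 45 of 48 developmental transcription factor genes (45; median -1.01, camera adjusted p = 0.19). Examples are the synaptic gene unc-13 (403 ± 110 against 964 ± 276), the muscle gene unc-89 (1380 ± 225 against 2663 ± 854) and the zinc-finger gene lin-29 (467 ± 114 against 1026 ± 388). Of 269 nuclear hormone receptor genes 246 fell (248 adjusted over the list alone; median -1.04, camera adjusted p = 0.20). Without mutant replicate 2 the neuronal, muscle and developmental lists were called as falling less than other genes on the spike-in scale (camera adjusted p = 0.023, 0.014 and 0.024), and without mutant replicate 1 the major sperm protein and muscle lists were (0.0098 and 0.049). With equal totals, an alternative chosen after seeing the data, the neuronal (median 0.04), muscle (0.10) and developmental (0.07) lists turned positive and were called higher than other genes (camera adjusted p = 0.0015, 5.1e-04 and 0.0011), which was lost with an estimated correlation (adjusted p = 0.22 for each). On that scale mutant replicate 2 lay closer to WT than to the other mutant libraries (Pearson r across genes 0.980 to 0.982 against 0.931 and 0.945), which bears on every list.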

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

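The alternatives with equal totals for gene lists, equal totals without mutant replicate 2 and equal totals without mitochondrial genes were chosen after seeing the data, and the others before. The genome-wide fall kept its direction under every alternative run, from -0.672 with the median pseudocount to -1.386 with the smallest, and from -0.885 to -1.32 when a library was left out. The difference between X and autosomes reversed to -0.016 with the log2 of the mean value (the cause was not tested), and fell to 0.045 with genes above the median level (exact permutation p = 0.4) and to 0.099 with the smallest pseudocount. Arms minus centres stayed between 0.062 (median pseudocount, exact permutation p = 0.2) and 0.247. On the spike-in scale the count of fallen genes was 8722 with only genes above the median level, where fewer genes were tested, and ranged from 2228 (without mutant replicate 1) to 18656 (without WT replicate 3) when a library was left out, with 2520 without mutant replicate 3 and 6936 without WT replicate 1. The single rise, rol-6, was called in all of these. Of the 53 called genes among the 63 tracked on that scale, 38, 39 and 33 lost their call without mutant replicate 1, mutant replicate 3 and WT replicate 1, csr-1 among those lost without mutant replicate 3. The calls relative to the library median (1010 fell, 901 rose) were sensitive to the scaling, more so than the changes behind them. There were 0 falls and 1 rise with the smallest pseudocount, with genes above the median level, with equal totals, with quantile normalization and with equal totals without mitochondrial genes. There were 2622 and 4009 with the median pseudocount, and 5992 and 2619 with equal totals without mutant replicate 2, of which 1010 and 432 were shared with the calls above. Leaving out single libraries gave 0 to 3239 falls and 1 to 5528 rises, the highest without mutant replicate 2 and 0 and 1 without any other. With equal totals the median change of the 1010 falls was -0.751 (median SE 0.189) in place of -0.594 (0.148), so a larger SE and fewer degrees of freedom (9.98 against 13.9 in the median gene) went with the lost calls, not a smaller change. The median of the 901 rises shrank from 0.634 (0.166) to 0.323 (0.150). Part of both shifts was a moved zero point, as the median of all genes went from 0.089 to -0.099. Among gene lists, 4 were lower and 6 higher than other genes, which became 0 and 0 with an estimated correlation. That estimate includes each library's shared factor. With equal totals, which removes that factor, no list was called with an estimated correlation either (lowest camera adjusted p = 0.22). Leaving out single libraries gave 4 lower throughout and 6 to 9 higher, 8 without mutant replicate 1 and 9 without mutant replicate 2. With fry, which makes no comparison with other genes, 16 were lower and 0 higher (adjusted p = 0.041), all but the collagens (adjusted p = 0.074). Gene deviations of same-numbered libraries did not correlate (-0.034, -0.02 and 0.028), but library levels ranked alike, so pairing stays open. With a replicate block 19810 genes fell and 1 rose on the spike-in scale, and 1715 fell and 2489 rose relative to the library median. Of the mutant libraries, replicate 3 correlated best with the WT library of its own number and replicates 1 and 2 did not, and 4 lists were lower and 6 higher, with muscle genes gained (camera adjusted p = 0.0089) and chemoreceptors lost (0.21). The edgeR test on recovered reads was not run, because 2 WT libraries had too few low values for the step to be tested. Depth limits the low genes of mutant replicate 3 most, with a median of 141 reads per gene and 32 genes at 0, and the unknown error of the spike-in factors limits every level.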

Other observations

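Of the tests in this part, the 10 splits of the libraries and the test on chromosome arms were set before their results were seen; the tests of one factor per library, mitochondrial yield, a wrong label, mixing, depth, the region around rol-6, collagen reads and extra rol-6 DNA were chosen after. Mitochondrial genes, whose DNA carries no histones, varied more between the mutant libraries than between WT libraries. They took 1.37%, 5.61% and 0.72% of the signal in mutant replicates 1 to 3 and 2.83%, 2.03% and 2.03% in WT replicates 1 to 3. Against the WT mean their level was 0.23, 1.44 and 0.11 in mutant replicates 1 to 3, where that of nuclear genes was 0.38, 0.56 and 0.35. The cytochrome oxidase gene ctc-1 had 8981 ± 10360 RRPM in the mutant and 15100 ± 5291 in WT (SD, n = 3 each). Per kb, arms held 25.4%, 10.2% and 30.3% more signal than centres in mutant replicates 1 to 3, and 3.6%, 5.8% and 3.6% more in WT replicates 1 to 3.

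The first pattern is the fall across the genome, with 17398 genes lower, where the highest of the other 9 splits gave 11; 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05. For the part common to all genes, a difference of -1.102 in median log2 level, one factor per library and a loss of H3K9me3 in proportion at every gene cannot be told apart, because both move all genes of a library alike; one factor as the whole account is argued against for mutant replicates 1 and 3, since with equal totals 1 gene was called over all 6 libraries but 43.1% of genes without mutant replicate 2. A lower yield of worm DNA against the spike-in, with or without the mark, cannot be told apart: mitochondrial signal differed by -1.55 on the log2 scale (exact permutation p = 0.4, n = 3 each), below all WT libraries in mutant replicates 1 and 3 and above all of them in replicate 2. A loss centred on the arms is argued against, since arms minus centres moved by 0.15 in the other direction and stayed above 0 under every alternative run (lowest 0.062 with the median pseudocount, exact permutation p = 0.2), although mutant replicate 2 (0.107) hardly exceeded WT replicate 2 (0.101); how to judge whether WT arms were richer was settled only after the result was seen, by their excess of 3.6% to 5.8% within each library, and the test reaches no further than that small excess. The csr-1a genotype stays open as the biological explanation.

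The second pattern is mutant replicate 2, whose profile with equal totals correlated at 0.980 to 0.982 with WT libraries and at 0.945 and 0.931 with mutant replicates 1 and 3 (Pearson r across genes, which are not independent). A WT sample under a mutant label is argued against by rol-6, which stood at 5.79 times the library median there and at most 1.5 times in WT. The signal over csr-1 was 5.09 times the library median there, above WT (3.9 to 4.46) and above mutant replicates 1 and 3 (3.31 and 2.44). That signal checks neither group label. Sampling noise from the lower depth of replicates 1 and 3 is argued against by their correlation with each other, 0.973, above that of either with any other library (0.945 at most). A systematic effect of low depth or yield common to both would also make them alike, so this correlation cannot decide on it. A mixture with WT cannot be told apart: replicate 2 lay 0.18 of the way from WT to the other mutant libraries over nuclear genes and 0.49 of the way at rol-6, and of 12 such gaps (3 ways over all genes and 1 over nuclear genes, each against 3 references) 10 exceeded the 0.25 set as the bound; it stays open because the 2 others, 0.21 and 0.22 with log2 values relative to the library median, did not, and the level of rol-6 in an unmixed replicate 2 is not known. Mitochondrial genes in replicate 2 stood at 1.44 of the WT mean, outside both the WT libraries (at most 1.22) and mutant replicates 1 and 3 (0.23 and 0.11). They enter the gaps counted over all genes. This rests on 1 library, so it does not settle the mixture. Relative to the library median, 1911 genes were called, where the highest other split gave 0 (1 of 10 splits reached the real count, again too few for a share under 0.05). The counts were 3239 falls and 5528 rises without mutant replicate 2 and 0 and 1 without any other.

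The third pattern is rol-6, at 271.1, 254.8 and 293.1 RRPM in mutant replicates 1 to 3 while the median gene of the same libraries ranged from 21.9 to 44.01. A wider region of higher signal is argued against by the nearest genes, the higher of which changed by -0.05 with equal totals. For reads shared among collagen genes, the highest of the 176 other collagens, col-39, was at 0.96 (SE 0.29), far below rol-6. It lay below the bound of 1 chosen to argue against such sharing, but by less than its SE. Shared reads therefore stay open. Extra rol-6 DNA in the mutant strain may explain it, as a rol-6 allele is a common marker in worm transgenesis: with equal totals its log2 change was 2.51 (SE 0.21; 2.66, 1.96 and 2.90 above the WT mean in mutant replicates 1 to 3), and no neighbour was above 0.02. A gain of H3K9me3 limited to rol-6 would give the same values and stays open.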
